A study of Mus musculus with 150 samples.

How the data were processed

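RNA of whole lung from 150 male mice was hybridised to Affymetrix HT MG-430 PM arrays, 1 array per mouse, so replicates are separate animals. The deposited values are log2 intensities, 1 per probe set and array, already background-corrected, normalised and summarised by RMA, per the submitters' processing notes, which also name Partek. Versions, and whether all plates were normalised together, are not given in the sources used here. Over 45037 probe sets the values ran from 1.74 to 14, with array medians from 3.95 to 4.26. Arrays give no read depth, and differences of genes near the dim end are compressed by background signal.

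Strain, dose, week and replicate number came from each sample's own labels, which gave 31 groups. The series design states 154 mice, of which 150 are analysed here. Array plates came from the well labels, with 88 arrays on plate 1, 14 on plate 2, 22 each on plates 3 and 4, and 4 on plate 3 or 4. A tumour note in the labels of 10 animals was read as it stands. The platform annotation lists 29449 probe sets. Of these 28898 have 1 gene, 551 have several and were left out, and 15588 probe sets not listed are unnamed here. Symbols of 28689 probe sets were updated through Entrez numbers in the GRCm38.p6 gene table, whose coordinates served to find the neighbours of Cyp2f2 and are not printed, as the array's build is not given in the sources used here. For the 7180 genes with more than 1 probe set, the one with the highest mean over all arrays stands for the gene, and the mean of all was the alternative.

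Of 17097 genes, 15695 were tested, after 1402 were removed that did not lie above the 30th percentile of an array's probe sets, a level of 2.99 to 3.19, in at least 3 arrays. No measure of detection per probe set was used here, so a fold of a gene whose mean on 1 side lay under this filter level is given as "at least", from the brighter mean against, on each array of the dimmer side, the higher of that level and the gene's value. All 31 group means and a term for plate 2 were fitted together with limma (lmFit and eBayes), and contrasts were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Every adjusted p of a gene is from limma. Styrene effects of 2 strains were subtracted within that model over the weeks both had. Averages over weeks to 78 left out 104 weeks, where dose and plate coincide. The tumour label was tested in CD-1 mice at 104 weeks with dose in the model. The 29 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation as the alternative. Counts adjusted over the list alone come from the same p-values.

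The rule for named genes, set like the tests and lists before the data were examined, allows the called genes with the 10 highest and 10 lowest differences in each comparison, up to 4 members of each list with the smallest p, Cyp2f2 and the clock genes. Genes followed across other comparisons were chosen after their values were seen. The alternatives set at the same time were no filter, a stricter filter at the 50th percentile in at least 50% of arrays, the mean of probe sets, C57BL/6 and CD-1 arrays fitted separately, eBayes with trend and robust, no plate term, plate 4 terms, other sets of weeks, replicate numbers as a block and each array left out of groups of 2 to 5. Fits with a covariate for the main axis of within-group differences, without the 2 arrays farthest along it, without tumour-labelled mice and of the tumour label within each dose were added after the data were seen. That axis is the first principal component of the deviations from group means in 102 arrays up to 78 weeks.

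The fits were tested on simulated data with 200 of 15695 genes changed. In the design of WT at 52 weeks, log2 changes of 0.5, 1 and 2 were recovered for 54.9%, 92.9% and 100% of genes, in that of WT at 78 weeks for 16.7%, 69.4% and 94.4%, and in that of the WT minus KO effect for 72.1%, 93.5% and 100%. With a within-group axis simulated at 104 weeks in WT, 3089 genes were called, 167 of them changed, and 152 with the covariate, 141 of them changed. The software was R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and matplotlib 3.10.9.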

Results

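Whole lungs of male mice were profiled after 26, 52, 78 or 104 weeks of inhaling air or 120 ppm styrene, an aromatic solvent that lung cytochrome P450 enzymes oxidise. The 150 arrays, 1 per mouse, covered 4 kinds of mice. These were 31 wild-type C57BL/6 mice (WT), 39 C57BL/6 mice without CYP2F2 (KO), 38 CYP2F2-null mice that carried a transgene labelled 2F1, SA13, 2B6 (TG) and 42 outbred CD-1 mice. Air was inhaled by 71 mice and styrene by 79, in 31 groups of 2 to 10. No WT air group at 26 weeks was analysed here, so WT had no exposure comparison then. The treatment label gives 6 h a day on 5 days a week, and its 1 or 4 weeks differ from each sample's own label, used here. The number of arrays limits precision. Up to 78 weeks arrays lay on plate 1, except 1 CD-1 styrene array at 26 weeks, 1 CD-1 air array at 52 weeks, and at 78 weeks 4 of 5 WT and all KO and TG styrene arrays, on plate 2. Only those CD-1 and WT groups held both plates, so they set the plate term, also for KO and TG. At 104 weeks air arrays lay on plate 3 and styrene arrays on plate 4, except 2 KO and 2 TG styrene arrays whose wells left the plate open.

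Cyp2f2, the targeted gene, is the club cell P450 that oxidises styrene. In air controls its level was 13.43 ± 0.07 (SD, n = 11) in WT and 12.11 ± 0.18 (n = 15) in KO mice of 52, 78 and 104 weeks, or 2.49-fold lower in KO (adjusted p = 6.18e-31). It was also 12.11 ± 0.15 (n = 19) in TG mice, against 12.12 ± 0.17 (n = 20) in KO mice of all 4 weeks (adjusted p = 0.999). Every KO and TG group mean lay between 12.05 and 12.40, and every WT and CD-1 group mean between 13.05 and 13.50. Whether the probe set lies in the deleted part is not given here, and a probe outside it would check nothing. Cyp2f2 was called in none of the 15 comparisons of styrene with air, at -0.21 (WT, 78 weeks) to 0.25 (KO, 26 weeks). All 5 exposed WT mice lay below the air mean at 52, 78 and 104 weeks, and 9 of 10 CD-1 mice above it at 104.

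**Figure D1:**
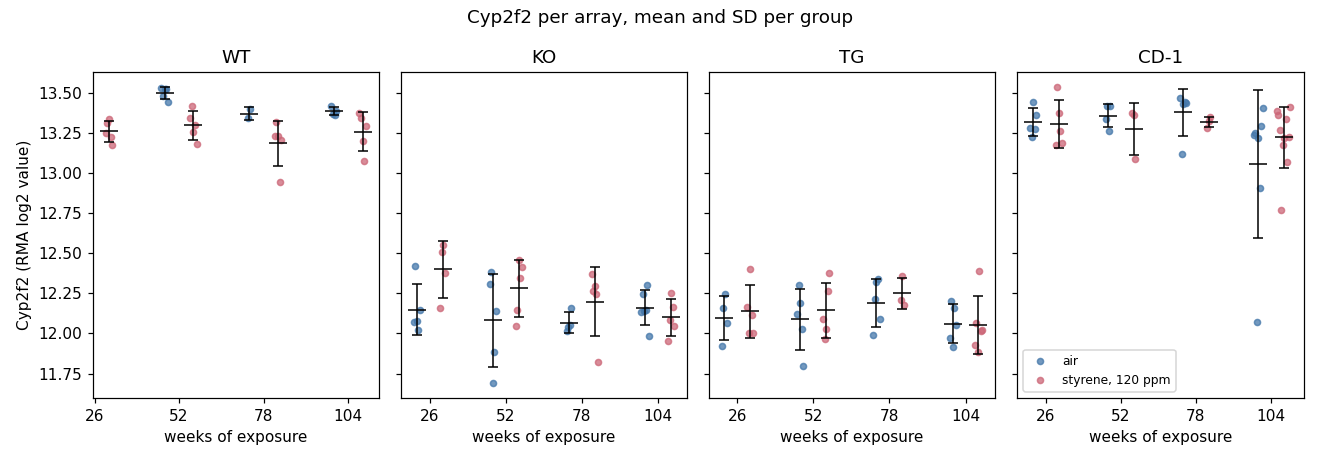
Cyp2f2 level (RMA log2 value, vertical axis) of each array against weeks of exposure for the 4 kinds of mice. Blue marks air and red 120 ppm styrene, with group means and SDs as bars. KO and TG group means sit below those of WT and CD-1.

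KO and WT air controls were compared at 52, 78 and 104 weeks. The carboxylesterase Ces1f was 6.74-fold lower in KO lungs (log2 -2.75, SE 0.215, adjusted p = 1.42e-20), and its relative Ces1g was 2.60-fold lower. Pttg1, which encodes securin, was 5.97-fold lower, at 9.11 ± 0.88 (n = 15) in KO against 11.73 ± 0.15 (n = 11) in WT. The acyl-CoA synthetase Acsm1, the glutathione peroxidase Gpx2 and the plasma protease inhibitor Fetub were lower by 2.28, 2.15 and 2.11 times. Lrmda and the actin-binding Cfl2 were 3.30-fold and 1.91-fold higher. Of 23 measured xenobiotic metabolism genes 3 were lower and none higher, and 5 were lower when adjusted over the list alone. Of 21 Nrf2 targets 2 were lower, as many as when adjusted over the list alone. Both lists lay below the other genes (camera adjusted p = 1.08e-11 and 6.96e-07). With an estimated correlation both calls were lost (adjusted p = 0.105 each). The 15 alveolar macrophage markers had a median difference of 0.36 (camera adjusted p = 6.65e-10), with no member called over all genes and 3 higher when adjusted over the list alone. That call too was lost, with adjusted p = 0.114 with an estimated correlation. In all, 50 of 15695 genes differed, 6 higher and 44 lower in KO, and 32 without the array of WT air 78 weeks replicate 2. Among 192 tested genes within 5 Mb of Cyp2f2, 2 were called, Cyp2f2 itself and Mia, against 48 of 15503 elsewhere (Fisher's exact test, two-sided, p = 0.125).

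Pttg1 again differed between TG and KO air controls, 4.61-fold higher in TG (11.42 ± 0.70, n = 19, against 9.18 ± 0.89, n = 20; log2 2.20, SE 0.194, adjusted p = 5.18e-17). Gdpd3, a lipid phosphodiesterase, averaged 5.76-fold higher in TG but varied widely between TG mice, at 8.13 ± 2.18 against 5.58 ± 0.33 in KO. The endosomal adaptor Wdfy1, Sec14l4 and the actin regulator Cap1 were higher in TG by 2.32, 2.04 and 1.71 times. Tceanc2, the Mediator subunit Med8 and the complement inhibitor Cd59a were lower by 3.03, 1.73 and 1.73 times. None of the 19 measured collagen and matrix genes passed the test, also when adjusted over the list alone. Their median was 0.13 higher in TG (camera adjusted p = 8.48e-06; 0.0759 with an estimated correlation). The 13 alveolar type 2 markers had 3 higher members when adjusted over the list alone and 0 over all genes (camera adjusted p = 5.16e-05; 0.175 with an estimated correlation). The comparison called 54 genes, 36 higher and 18 lower in TG, and 35 without TG air 26 weeks replicate 4. Of these 54, 13 also differed between KO and WT, 12 in the opposite direction, though TG mice also lack CYP2F2.

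CD-1 and WT air controls compared outbred with inbred lung. Serpina1b, an alpha-1-antitrypsin gene, was 36.5-fold higher in CD-1 (8.69 ± 0.46, n = 16, against 3.50 ± 0.56, n = 11; log2 5.19, SE 0.307, adjusted p = 1.22e-30). Tmem87a, Fbp2, the B cell adaptor Pik3ap1 and the interferon-inducible Ifi202b were higher by 17.4, 11.2, 9.20 and at least 5.41 times, as Ifi202b averaged under the filter level in WT. The peptide transporter Slc15a2, Nxpe4, Azgp1 and Pttg1 were lower by 16.2, 14.3, 10.4 and 8.12 times. Of 15 club cell markers 7 were lower in CD-1, as many as when adjusted over the list alone. Of 16 ciliated cell markers 6 were lower, or 9 when adjusted over the list alone, and no member of either list was higher (camera adjusted p = 0.00201 and 0.00403). Of 15 alveolar macrophage markers 6 were higher, and when adjusted over the list alone 6 were higher and 1 lower (camera adjusted p = 0.00504). All 3 list calls were lost, with adjusted p = 0.759 with an estimated correlation. In total 2732 genes were called, 1082 higher and 1650 lower in CD-1, and 1814 without WT air 78 weeks replicate 2. A probe set can read a strain's sequence variant as a level, so these are differences of hybridisation signal.

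Serpind1, which encodes heparin cofactor II, rose with styrene at all 4 weeks in CD-1 mice. It was 7.57-fold higher with styrene at 26 weeks (7.33 ± 0.41, n = 5, against 4.41 ± 0.23, n = 5), 4.46-fold at 52 weeks, 7.99-fold at 78 weeks and 7.29-fold at 104 weeks. All 5, 3, 3 and 10 exposed mice lay above the air mean of their week. The log2 differences were 2.92 (SE 0.259, adjusted p = 1.9e-16), 2.16 (SE 0.313, adjusted p = 4.28e-06), 3.00 (SE 0.293, adjusted p = 6.12e-14) and 2.87 (SE 0.198, adjusted p = 4.08e-24). In WT mice it rose 2.08-fold at 52 weeks (5.75 ± 0.16 against 4.69 ± 0.35, n = 5 each, adjusted p = 0.0323), a call lost without any 1 of 7 arrays named with that comparison, and 3.35-fold at 104 weeks (adjusted p = 2.52e-07). At 78 weeks, with 2 air controls, its 1.69 log2 difference did not pass (adjusted p = 0.308), though all 5 exposed mice lay above the air mean. In KO mice the differences were -0.07, -0.09, -0.03 and 0.20, and in TG mice 0.07, -0.48, 0.02 and -0.16, none of them called. Serpind1 was followed in the KO and TG mice, and in WT at 78 and 104 weeks, after its values in the other comparisons had been seen.

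**Figure D2:**
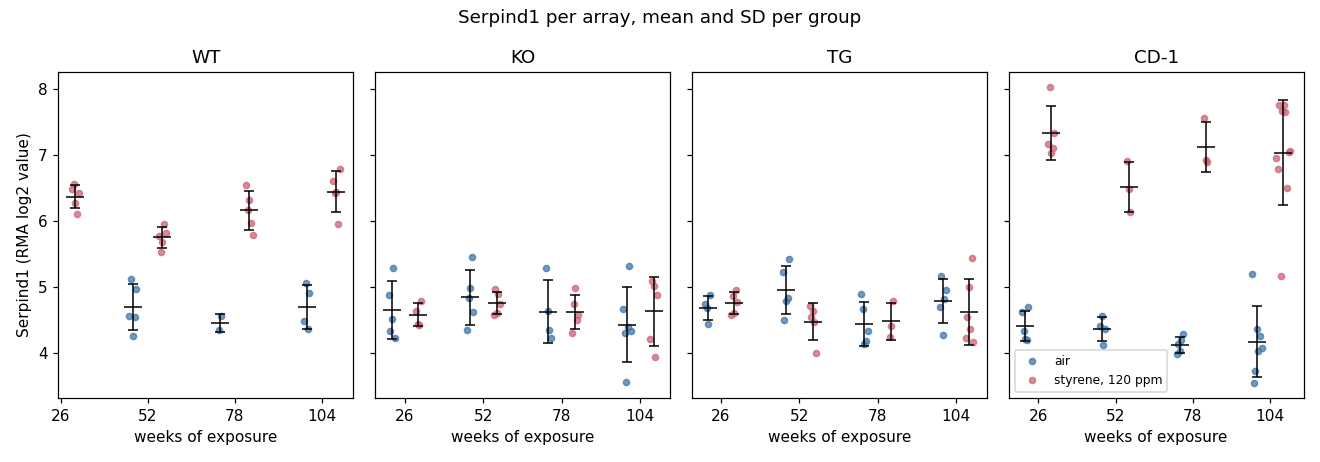
Serpind1 level (RMA log2 value, vertical axis) of each array against weeks of exposure for the 4 kinds of mice, with blue points for air and red for 120 ppm styrene, and the mean and SD of each group as bars. Exposed CD-1 group means lie between 6.51 and 7.33 and exposed WT means between 5.75 and 6.44, while exposed KO and TG means lie between 4.47 and 4.76, among those of their air controls.

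The exposure effects of WT and KO mice were set against each other directly, averaged over 52, 78 and 104 weeks, to find responses that differ with CYP2F2. The effect on Serpind1 was larger in WT by 1.47 (log2, SE 0.223, adjusted p = 1.84e-05) and that on Ces1g by 1.39 (SE 0.250, adjusted p = 0.000538). Kininogen, Kng1, and the transcription factor Tcfl5 and opsin gene Opn3 also had larger effects in WT, by 1.28, 0.94 and 0.56, although Kng1 averaged under the filter level in 25 and Tcfl5 in 16 of 31 groups. The asialoglycoprotein receptor subunit Asgr1, the lipoprotein-bound esterase Pon1 and the tight junction gene Cldn8 had lower effects in WT, by -2.03, -1.47 and -1.21, as had Ces1f, Mfsd4a, Itih2, A930001A20Rik, Camk2b and Acss1. For Asgr1 all 5 exposed WT mice of each week lay below the air mean, with differences of -2.03, -2.18 and -1.46, against 0.06, -0.20 and 0.56 in KO, values looked up after the test. The 17 cholesterol and lipid synthesis genes had a median of 0.20, with no member called, also when adjusted over the list alone (camera adjusted p = 3.18e-07; adjusted p = 0.22 with an estimated correlation). Of 15 club cell markers 2 had lower effects in WT when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000769; adjusted p = 0.575 with an estimated correlation). These 14 genes, 5 with larger and 9 with lower effects in WT, became 5 without WT air 78 weeks replicate 2. That left Kng1, Tcfl5, Cldn8 and Ces1f at adjusted p = 0.135, Acss1 at 0.114, Itih2 at 0.0978, Opn3 and A930001A20Rik at 0.0517 and Camk2b at 0.406. Without WT air 78 weeks replicate 1, Kng1, Tcfl5 and Opn3 were lost (adjusted p = 0.0653, 0.071 and 0.1). Kng1 also went without WT styrene 78 weeks replicate 4, WT styrene 104 weeks replicate 1 or KO air 78 weeks replicate 1 (adjusted p = 0.0507, 0.0517 and 0.102). Tcfl5 went without WT styrene 52 weeks replicate 4, WT air 104 weeks replicate 1, WT styrene 104 weeks replicate 1 or KO air 78 weeks replicate 3 (adjusted p between 0.052 and 0.0556), and Camk2b without 11 of the 50 arrays. The count was 28 without the mice labelled with a tumour, 30 when the C57BL/6 arrays were fitted alone, where Camk2b had adjusted p = 0.0596, and 22 with a covariate for the main axis along which arrays of 1 group differ, described with the 104-week data. As the mean of all its probe sets, Kng1 was no longer called (0.80, adjusted p = 0.364), nor was Acss1 (adjusted p = 0.985). Kng1 was not called without the 2 arrays farthest along that axis (adjusted p = 0.0952), nor Opn3 with a plate 4 term that places 2 KO arrays on plate 3 (adjusted p = 0.0702).

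No gene's exposure effect differed between TG and KO mice over the 4 weeks by limma, with 646 genes at unadjusted p under 0.05. The 16 ciliated cell markers had a lower median effect in TG (-0.32, none called, also when adjusted over the list alone; camera adjusted p = 1.41e-06; adjusted p = 0.596 with an estimated correlation). The heart muscle markers were lower in the same contrast (median -0.54 over 12 genes, 0 called, also when adjusted over the list alone; camera adjusted p = 2.75e-05; adjusted p = 0.596 with an estimated correlation). For Serpind1 the TG minus KO effect was -0.14 (SE 0.185, adjusted p = 1). The axis covariate gave 1 gene.

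Exposure raised Serpind1 more in CD-1 than in WT mice, by 1.18 over 52, 78 and 104 weeks (log2, SE 0.246, adjusted p = 0.0189). The alkenal reductase Ptgr1 and the glutathione transferase Gsta2 had effects larger in CD-1 by 0.60 and 1.04, and A930001A20Rik, Rhbg and Pak6 by 1.00, 0.84 and 0.75. Hsf2bp, Esyt3, Ascc2, Acss1 and Hsd17b6 differed by 0.44 to 0.66 in the same direction, Hsd17b6 under the filter level in 23 of 31 groups. Of 15 club cell markers 0 were called over all genes and 6 had larger effects in CD-1 when adjusted over the list alone (camera adjusted p = 5.68e-05; adjusted p = 0.7 with an estimated correlation). All 11 called genes had larger effects in CD-1. The count fell to 1 without WT air 78 weeks replicate 2, to 2 without CD-1 styrene 52 weeks replicate 1 and to 3 without CD-1 styrene 78 weeks replicate 1, and was 23 without CD-1 styrene 52 weeks replicate 3. It was 5 without WT air 52 weeks replicate 2 or WT air 78 weeks replicate 1, 6 without WT air 52 weeks replicate 3, WT air 104 weeks replicate 3, WT styrene 104 weeks replicate 4 or CD-1 styrene 78 weeks replicate 3, and 7 without WT styrene 52 weeks replicate 5, WT styrene 78 weeks replicate 4, CD-1 styrene 52 weeks replicate 2 or CD-1 air 78 weeks replicate 3. Without a plate term it was 17, with the mean of each gene's probe sets 5 and with the axis covariate 7. Serpind1 lost its call without WT air 78 weeks replicate 2 (1.14, adjusted p = 0.0837), CD-1 styrene 52 weeks replicate 1 (1.11, adjusted p = 0.0743) or CD-1 styrene 78 weeks replicate 1 (1.10, adjusted p = 0.0599). Ptgr1 lost it without the first or second of these (adjusted p = 0.0837 and 0.0501) and Pak6 without the first (adjusted p = 0.064). Gsta2, Esyt3, Hsf2bp, Rhbg, Hsd17b6, Acss1 and Ascc2 were lost without 24, 24, 20, 16, 9, 6 and 5 of the 41 single arrays, and A930001A20Rik without none of them. The mean of probe sets also ended the calls of Gsta2, Rhbg, Pak6, Hsf2bp, Esyt3, Acss1 and Hsd17b6 (adjusted p between 0.0528 and 0.826). The axis covariate ended those of Gsta2, Rhbg, Hsf2bp, Esyt3 and Hsd17b6 (adjusted p between 0.0622 and 0.106), and a fit without a plate term those of Pak6, Hsf2bp and Hsd17b6 (adjusted p between 0.0592 and 0.123). Leaving out mice labelled with a tumour ended those of Rhbg and Esyt3 (adjusted p = 0.0523 and 0.0575). Without a filter, or with a plate 4 term that places 2 KO arrays on plate 3, Gsta2 and Esyt3 missed the threshold (adjusted p between 0.0507 and 0.0511).

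In WT mice at 52 weeks, Asgr1 was 4.08-fold lower with styrene (3.75 ± 0.31 against 5.77 ± 0.43, n = 5 each; log2 -2.03, SE 0.394, adjusted p = 0.00769) and was below the air mean in 5 of 5 exposed mice. Pon1, Cldn8, Gsta2 and the cholecystokinin receptor Cckar were lower by 2.29, 2.23, 2.14 and 1.76 times. Among the genes that rose were Serpind1, the microtubule protein Map1b by 2.39 times and the nuclear proteins Srrm2, Crebbp and Chd4 by 1.91, 1.80 and 1.80 times. With the mean of all their probe sets, Map1b (0.41, adjusted p = 0.206) and Srrm2 (0.55, adjusted p = 0.0698) were not called. Of 15 club cell markers 1 fell, or 3 when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.00012; adjusted p = 0.616 with an estimated correlation). Of 19 collagen and matrix genes 1 rose, or 3 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 1.68e-06; adjusted p = 0.0468 with an estimated correlation). The 12 heart muscle markers, transcripts of tissue that can be carried along with a lung, had a median of 0.81 with no member called, also when adjusted over the list alone (camera adjusted p = 8.07e-05; adjusted p = 0.616 with an estimated correlation). The comparison called 63 genes, 26 higher and 37 lower, a balance that turned without air replicate 2 (11 and 4) or 3 (20 and 14) and under a stricter filter on dim genes (25 and 15). This count fell to 39, 15, 34 and 18 without air replicates 1, 2, 3 and 4, and to 35, 6, 18 and 3 without styrene replicates 1, 3, 4 and 5. Serpind1 lost its call without air replicate 1, 3 or 4 (adjusted p = 0.0606, 0.117 and 0.0794) or styrene replicate 1, 3, 4 or 5 (adjusted p = 0.0526, 0.0589, 0.0924 and 0.0913). Pon1 and Gsta2 lost it without air replicate 2 or styrene replicate 3 or 5, and Srrm2 without air replicate 5 or styrene replicate 3 or 5 (adjusted p between 0.0532 and 0.0913). Cldn8 and Crebbp were lost without 8 of the 10 arrays each, Map1b and Chd4 without 6 each and Cckar without 4, while Asgr1 kept its call without any 1 array. Counts were 40 under that filter, 124 with C57BL/6 arrays alone and 183 with the axis covariate.

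Ces1g was the 1 gene called in WT at 78 weeks, 4.80-fold higher with styrene (7.79 ± 0.60, n = 5, against 5.61 ± 0.36, n = 2; log2 2.26, SE 0.443, adjusted p = 0.0188), above the air mean in 5 of 5 exposed mice. Of 14 measured immediate-early genes, such as those of the Fos and Egr families, 0 were called over all genes and 6 fell when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 8.3e-10; adjusted p = 0.0642 with an estimated correlation). Heart muscle markers had a median of 1.43 beside this, 0 of 12 called, also when adjusted over the list alone (camera adjusted p = 7e-05; adjusted p = 0.754 with an estimated correlation). With 4 of the 5 exposed arrays on plate 2, the plate term enlarged these differences: that of the myoglobin gene Mb was 2.24 with it (adjusted p = 0.999) and 1.11 without it (7.74 against 6.63), when the list had adjusted p = 0.0394. Ces1g lost its call without air replicate 1 (2.01, adjusted p = 1) or 2 (2.52, adjusted p = 0.157), when the lone air array was taken to vary like the other groups. It also lost it without styrene replicate 1 (1.60, adjusted p = 0.821), so 0 genes then passed. The count was 2 without a plate term and with C57BL/6 arrays alone.

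Averaged over 52 and 78 weeks, WT mice showed 6 called genes, 1 higher and 5 lower with styrene. Serpind1 rose by 1.37 (log2, SE 0.235, adjusted p = 0.000498), Asgr1 fell by 2.10 (SE 0.365, adjusted p = 0.000498) and Pon1, the protease Capn13 and the mitochondrial acetyl-CoA synthetase Acss1 fell by 1.15, at least 0.38 and 0.45, as Capn13 averaged 2.90 with styrene, under the filter level. As the mean of its probe sets Acss1 was not called (-0.12, adjusted p = 0.994). Of 15 club cell markers 1 fell when adjusted over the list alone and 0 over all genes, with a median of -0.39 (camera adjusted p = 2.05e-05; adjusted p = 0.313 with an estimated correlation). Of 12 heart muscle markers 5 rose when adjusted over the list alone and 0 over all genes, with a median of 1.14 (camera adjusted p = 8.95e-10; adjusted p = 0.137 with an estimated correlation). Without WT air 78 weeks replicate 1 or 2 the count was 3 or 1, with Pon1 at adjusted p = 0.183 or 0.402 and Capn13 at 0.185 or 0.12. Serpind1 and Pon1 missed the threshold without WT styrene 78 weeks replicate 1 (adjusted p = 0.0508 each), Pon1 also without WT styrene 52 weeks replicate 5 (adjusted p = 0.0705), Asgr1 without WT air 78 weeks replicate 2 (-1.91, adjusted p = 0.12) and Acss1 without 8 of the 17 arrays. With C57BL/6 arrays alone Asgr1, Pon1, Capn13 and Acss1 were not called (adjusted p = 0.0727, 0.17, 0.389 and 0.138), nor was Capn13 with 104 weeks included (adjusted p = 0.0582). The count was 11 without a plate term, 72 for 52 weeks, the week with both doses on plate 1, in a fit without the plate 2 arrays and term, and 122 with 104 weeks included.

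Genes of the circadian clock stood out in CD-1 mice at 26 weeks. Dbp, a transcription factor driven by the clock, was 18.6-fold higher with styrene (9.38 ± 0.27 against 5.09 ± 1.47, n = 5 each; log2 4.21, SE 0.674, adjusted p = 1.09e-05), above the air mean in 5 of 5 exposed mice. Nr1d2 and Hlf were higher by 4.71 and 3.77 times and Per3 by 2.07 on the log2 scale. Arntl, which encodes BMAL1, was 7.90-fold lower, also in 5 of 5 mice, and Npas2 and Nfil3 were lower by 6.48 and 2.81 times. Of the 11 measured genes of the Dbp arm 7 rose, or 10 when adjusted over the list alone, and of 5 genes of the Bmal1 arm 3 fell, or 4 when adjusted over the list alone. Both lists were called (camera adjusted p = 1.4e-28 and 1.21e-15), also with an estimated correlation (adjusted p = 5.88e-05 and 2.7e-06). Besides Serpind1, the plasma protein gene Azgp1 and the esterase Ces1g rose by 3.77 and 5.20 times, the synaptic pentraxin Nptx1 by 7.56 times and the plasma protein gene Kng1 by at least 2.94 times. The matrix protein Spon2 fell by 4.99 times and the chemokine Cxcl5 by at least 3.14 times. Kng1 in air and Cxcl5 with styrene averaged 2.40 and 2.66, under the filter level. Of 19 collagen and matrix genes 1 fell, also when adjusted over the list alone (median -0.26, camera adjusted p = 7.06e-06; adjusted p = 0.0374 with an estimated correlation). Of 21 Nrf2 targets 3 rose, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.00157; adjusted p = 0.381 with an estimated correlation). In all, 102 genes were called, 53 higher and 49 lower. The count was 61 and 67 without styrene replicates 2 and 3, the first of which ended the call of Cxcl5 (-2.02, adjusted p = 0.0517), and 175 with the axis covariate. It was 21 with CD-1 arrays alone, when Hlf, Azgp1, Nptx1 and the Nrf2 list lost their calls (adjusted p = 0.0927, 0.256, 0.0732 and 0.0683).

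**Figure D3:**
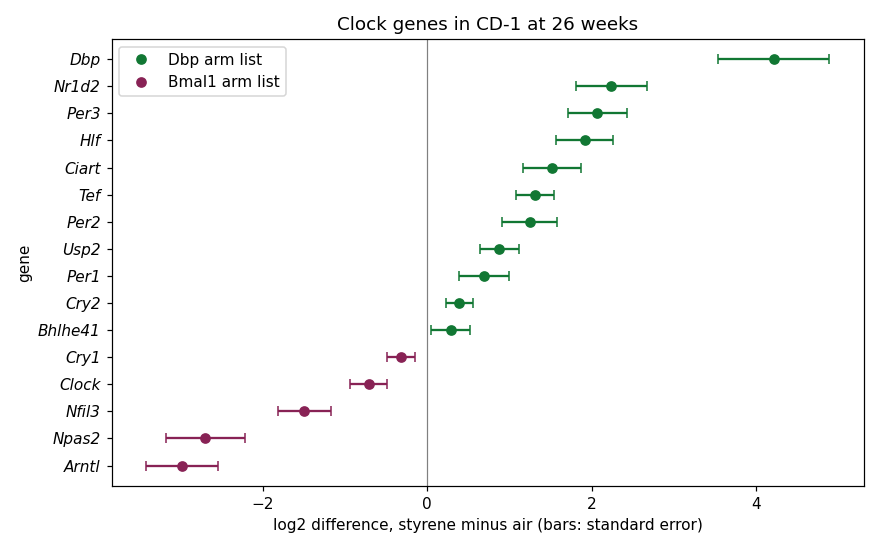
Log2 difference of styrene minus air (horizontal axis, bars: standard error) for the 16 measured members of the clock lists in CD-1 mice at 26 weeks, 5 mice per dose. The Dbp arm lies on the side of higher values, led by Dbp at 4.21, and the Bmal1 arm on the side of lower values, led by Arntl at -2.98.

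At 52 weeks the CD-1 response held 11 genes, 8 higher and 3 lower. Beside Serpind1, the zinc finger gene Zbtb7a and the chromatin remodeller Chd4 rose by 2.50 and 2.35 times, and the Golgi protein Glg1 and integrin alpha 2, Itga2, fell by 2.31 and at least 1.77 times (3 exposed against 4 air mice). Dbp and Arntl differed by 0.01 and -0.13 there (SE 0.815 and 0.532), neither called. Ces1g and Fetub differed by 0.53 and 0.54 (adjusted p = 0.978 each), and Kng1, under the filter level in air, by at least 0.23 (adjusted p = 0.916). The number of genes was 17 without styrene replicate 1, 3 with CD-1 arrays alone and 18 with the axis covariate. Chd4 lost its call without air replicate 2 (1.05, adjusted p = 0.0762) or styrene replicate 2 (1.11, adjusted p = 0.134), and Zbtb7a without the same arrays (adjusted p = 0.361 and 0.471) or without a plate term (adjusted p = 0.0756). Itga2 lost it without styrene replicate 2 (-0.83, adjusted p = 0.0655) and Glg1 with the mean of its probe sets (-0.47, adjusted p = 0.099), and Zbtb7a, Glg1 and Itga2 with CD-1 arrays alone (adjusted p = 0.336, 0.999 and 0.542).

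At 78 weeks Serpind1 and Kng1 rose again in CD-1 mice, Kng1 by at least 3.02 times (adjusted p = 0.000117; 4.63 ± 1.38, n = 3, against an air mean of 2.39, under the filter level; above it in 3 of 3 exposed mice). Ces1g, Fetub and Ptgr1 rose by 2.67, 2.57 and 1.84 times. Ifi205, Ifi203 and Ddx60, each known to be induced by interferon, were lower, Ifi205 by 11.4 times (3.58 ± 0.47, n = 3, against 7.10 ± 1.47, n = 5), Ifi203 by 2.90 times and Ddx60 by 2.04 times. Of the fixed list of 20 measured interferon response genes 0 were called, with a median of -0.34, also when adjusted over the list alone (camera adjusted p = 2.24e-05; adjusted p = 0.454 with an estimated correlation), and this call ended without air replicate 3 (adjusted p = 0.193). Of 21 Nrf2 targets 3 rose when adjusted over the list alone and 0 over all genes (median 0.20, camera adjusted p = 0.000117; adjusted p = 0.454 with an estimated correlation). The count of 19 genes, 13 higher and 6 lower, was 35 (15 higher and 20 lower), 120 (39 and 81) and 11 without air replicates 1, 2 and 3 and 10 without styrene replicate 1 or 3, the last of which also ended the call of Kng1 (adjusted p = 0.0916). Ces1g lost its call without air replicate 3 or 4, Fetub without air replicate 3 or 5, Ddx60 without air replicate 3 or 5 and Ifi203 without air replicate 3 (adjusted p between 0.0506 and 0.205). These 4 also lost it without styrene replicate 1 or 3, and all but Ifi203 without styrene replicate 2 (adjusted p between 0.065 and 0.247). The count was 3 with CD-1 arrays alone, where Kng1, Ces1g, Fetub, Ptgr1, Ifi205, Ifi203 and Ddx60 were not called, 10 under the stricter filter, 37 with the mean of all probe sets and 42 without the 2 arrays farthest along the axis. Ces1g and Fetub each had adjusted p = 0.0808 with the axis covariate.

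Averaged over 26, 52 and 78 weeks, 131 genes differed in CD-1 mice, 107 higher and 24 lower (78 and 34 with the axis covariate). Serpind1 was 6.46-fold higher (log2 2.69, SE 0.165, adjusted p = 2.5e-28; n = 11 exposed and 14 air mice), and Azgp1, Ces1g and Fetub were higher by 3.11, 2.72 and 2.23 times and Kng1 by at least 2.18 times. The aryl hydrocarbon receptor target Cyp1a1 and the chemokine Cxcl17 rose by 2.26 and 1.98 times. Cxcl5 was at least 2.38-fold lower, and the secretoglobin Scgb3a1 and Pon1 fell by 1.44 and 0.64 (log2). Of the clock genes, Dbp was 3.73-fold higher and Arntl fell by 1.41. In the Dbp arm 3 of 11 genes rose, or 9 when adjusted over the list alone (camera adjusted p = 8.34e-10; adjusted p = 0.0815 with an estimated correlation), and in the Bmal1 arm 3 of 5 fell, or 4 when adjusted over the list alone (camera adjusted p = 2.16e-06; adjusted p = 0.014 with an estimated correlation). Scgb3a1 and Pon1 lost their calls with the axis covariate (adjusted p = 0.0588 and 0.136), without 11 and 15 of the 25 single arrays and with CD-1 arrays alone (adjusted p = 0.396 and 0.372), where Cyp1a1 and Dbp were not called either (adjusted p = 0.0957 each). Scgb3a1 was also lost without the plate 2 arrays (adjusted p = 0.0639). Without CD-1 styrene 52 weeks replicate 2 Dbp was not called (1.64, adjusted p = 0.0798), nor Cyp1a1 without CD-1 styrene 78 weeks replicate 1 (0.96, adjusted p = 0.0513). The count was 81 without CD-1 styrene 26 weeks replicate 2, 68 without CD-1 air 52 weeks replicate 3, 60 without CD-1 styrene 52 weeks replicate 2, 83 without CD-1 air 78 weeks replicate 3 and 69 without CD-1 styrene 78 weeks replicate 3. It was 22 with CD-1 arrays alone, 69 without the plate 2 arrays and term and 5084 with 104 weeks included.

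KO mice at 26 weeks had no gene called by limma, with 363 at unadjusted p under 0.05, yet their clock lists shifted. Dbp averaged 7.89 ± 0.97 (n = 4) with styrene and 5.22 ± 0.96 (n = 5) in air (log2 2.67, SE 0.700, adjusted p = 0.978), above the air mean in 4 of 4 exposed mice, and Arntl was lower by -1.21 (adjusted p = 0.999). Of 11 genes of the Dbp arm 8 rose when adjusted over the list alone, and of 5 of the Bmal1 arm 3 fell when adjusted over the list alone, with 0 of either called over all genes. The camera adjusted p was 1.93e-20 and 1.84e-06, or 0.00237 and 0.00653 with an estimated correlation. With C57BL/6 arrays alone 1 gene was called.

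At 52 weeks, Sec14l4 and Wdfy1 were called in KO mice, higher with styrene by 4.25 times (log2 2.09, SE 0.396, adjusted p = 0.00475) and 2.76 times (log2 1.46, SE 0.270, adjusted p = 0.00472). Both differed in KO air controls from WT and from TG ones, and varied widely among the KO air mice, with SDs of 1.42 and 0.73 (n = 5). A styrene effect is thus uncertain. The 19 inflammation genes had a median of -0.56 and the 10 neutrophil markers one of -0.82, with 0 members called in either, also when adjusted over the list alone (camera adjusted p = 1.32e-08 and 4.72e-07; each adjusted p = 0.103 with an estimated correlation). The neutrophil call ended without air replicate 5 (adjusted p = 0.075). Sec14l4 lost its call without air replicate 1, 2 or 4 (adjusted p = 0.0555, 0.134 and 0.18) or styrene replicate 2, 4 or 5 (adjusted p = 0.0681, 0.0535 and 0.07), and Wdfy1 without air replicate 4 or styrene replicate 2 (adjusted p = 0.0603 and 0.0687). The count of 2 genes was 1 without air replicate 1 and without styrene replicate 4 or 5, and 0 without air replicate 4 or styrene replicate 2 or with C57BL/6 arrays alone, where both had adjusted p = 0.108 and 0.0724.

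At 78 weeks 0 genes were called in KO mice by limma, with 553 at unadjusted p under 0.05. Glucocorticoid response genes had a median of -0.37 (13 measured) and heart muscle markers one of 1.29 (12 measured), 0 called in either, also when adjusted over the list alone. The camera adjusted p was 2.32e-05 and 2.38e-05, or 0.294 and 0.642 with an estimated correlation. Exposed and air mice lay on different plates here, so other strains set the plate term. Without it both list calls ended (adjusted p = 0.637 and 0.494), the first also with C57BL/6 arrays alone (adjusted p = 0.396). Averaged over 26, 52 and 78 weeks, KO mice had 0 called genes by limma, with 946 at unadjusted p under 0.05. Of 19 inflammation genes 3 fell when adjusted over the list alone and 0 over all genes (median -0.28, camera adjusted p = 2.32e-08; adjusted p = 0.0852 with an estimated correlation), and of the Dbp arm 5 of 11 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.52e-06; adjusted p = 0.208 with an estimated correlation). The count was 1 without the plate term, with 104 weeks included, with the axis covariate, and without KO air 26 weeks replicate 1, KO styrene 52 weeks replicate 3 or KO styrene 78 weeks replicate 2, and 5 over 26 and 52 weeks without the plate 2 arrays and term.

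TG mice at 26 weeks had 0 called genes by limma, with 366 at unadjusted p under 0.05. Heat shock genes had a median of -0.50 (10 measured, 0 called, also when adjusted over the list alone; camera adjusted p = 3.05e-09; adjusted p = 0.0634 with an estimated correlation). The Bmal1 arm had a median of -0.52 (5 measured, 0 called, also when adjusted over the list alone; camera adjusted p = 1.94e-05; adjusted p = 0.044 with an estimated correlation).

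At 52 weeks, the salivary protein gene Bpifa2 averaged 5.30 ± 3.10 in exposed TG mice against 3.08 ± 0.33 in air (n = 5 each; adjusted p = 0.00194), and without styrene replicate 1 the difference was 0.94 (adjusted p = 0.0692). Ormdl2, a regulator of sphingolipid synthesis, fell by 0.42 (log2, SE 0.086, adjusted p = 0.0302), a call lost without air replicate 4 or 5 (adjusted p = 0.1 and 0.153) or styrene replicate 4 or 5 (adjusted p = 0.124 and 0.253). Of 15 alveolar macrophage markers 4 fell when adjusted over the list alone and 0 over all genes, with a median of -0.58 (camera adjusted p = 0.000277; adjusted p = 0.774 with an estimated correlation), a call that ended without air replicate 5 (adjusted p = 0.263). The 2 called genes became 4, 1 and 1 without air replicates 2, 4 and 5, 9 and 12 without styrene replicates 2 and 3, 1 under the stricter filter, 11 with the axis covariate and 10 without the 2 arrays farthest along the axis.

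At 78 weeks, the genes called in TG mice included Ctsg, Mpo, Klf1 and Rhd, with differences carried by 1 exposed mouse. The granule protease Ctsg and peroxidase Mpo averaged 4.04 ± 1.86 and 4.93 ± 2.58 in 3 exposed mice against 2.67 ± 0.10 and 2.81 ± 0.12, under the filter level, in 5 air mice. The erythroid genes Klf1 and Rhd averaged 4.44 ± 1.71 and 4.66 ± 1.84 against 3.19 ± 0.14 and 3.23 ± 0.19. Neither fixed list of such cells was called: of 10 neutrophil markers 0 and of 5 erythroid markers 0 passed, or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.805 and 0.348). Without styrene replicate 2, Mpo, Ctsg, Klf1 and Rhd differed by 0.69, 0.31, 0.30 and 0.42 (adjusted p = 0.993 each) and 0 genes were called. Without air replicate 1 or 4, Ctsg, Klf1 and Rhd also lost their calls, as Klf1 and Rhd did without air replicate 3 or 5 (adjusted p between 0.0527 and 0.11), and Klf1 without a filter (adjusted p = 0.0519). Of 13 glucocorticoid response genes 3 fell when adjusted over the list alone and 0 over all genes, and of 16 ciliated cell markers 0 either way. Each list had a median of -0.45, camera adjusted p = 0.00652, and adjusted p = 0.945 with an estimated correlation. The glucocorticoid call ended without styrene replicate 1 (adjusted p = 0.226), without the plate term (adjusted p = 0.762) and with C57BL/6 arrays alone (adjusted p = 0.419), and the ciliated call with C57BL/6 arrays alone (adjusted p = 0.722) and with the axis covariate (adjusted p = 0.225). The 30 called genes, 18 higher and 12 lower, were 6, 49, 16, 8 and 10 without air replicates 1 to 5 and 2846 and 343 (145 higher and 198 lower) without styrene replicates 1 and 3. Exposed mice lay on plate 2 and air mice on plate 1, so the plate term came from CD-1 and WT mice. Without it 7341 genes were called and under the stricter filter 12 (3 higher and 9 lower). With C57BL/6 arrays alone, with the axis covariate or without the 2 arrays farthest along the axis, 0 were called.

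Averaged over 26, 52 and 78 weeks, TG mice had 0 called genes by limma, with 2104 at unadjusted p under 0.05. The count was 2366 without the plate term and 834 and 144 without TG styrene 78 weeks replicates 1 and 3. It was 2 without TG styrene 52 weeks replicate 3, and 1 without TG air 26 weeks replicate 4, TG styrene 26 weeks replicate 2, TG air 52 weeks replicate 3 or TG styrene 52 weeks replicate 2.

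Styrene and air differed in many genes at 104 weeks in WT, KO and CD-1 mice. In CD-1, with 10 exposed and 7 air mice, among the highest increases were those of Serpind1, Azgp1, Ces1g and Fetub, by 7.29, 6.58, 6.06 and 5.95 times. Kng1 rose by at least 4.12 times, from an air mean of 2.48 under the filter level to 5.11 ± 0.85. Kng1, Ces1g and Fetub lay above the air mean in 10 of 10 exposed mice each. Of the clock genes, Dbp was 4.82-fold higher (log2 2.27, SE 0.515, adjusted p = 7.68e-05) and Arntl fell by 1.55 (log2, SE 0.336, adjusted p = 3.66e-05), each in 9 of 10 exposed mice against the air mean. The detoxifying enzymes Aldh3a1 and Gpx2 and the acyl-CoA synthetase Acsm1 rose by 4.05, 3.61 and 3.72 times. The MHC class II gene H2-Eb1 and the B cell gene Ms4a1 fell by 5.00 and 4.89 times. Of 21 Nrf2 targets 17 rose, or 18 when adjusted over the list alone, with none lower (median 0.49, camera adjusted p = 0.000278; adjusted p = 0.933 with an estimated correlation). Of 27 cell cycle genes 16 fell, also when adjusted over the list alone (median -0.54, camera adjusted p = 5.62e-05; adjusted p = 0.985 with an estimated correlation), a list not called without the mice labelled with a tumour (adjusted p = 0.93) or under the stricter filter (adjusted p = 0.0504). The comparison called 9977 genes, 6724 higher and 3253 lower, and 7629 without the mice labelled with a tumour.

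In WT mice at 104 weeks, Ces1g and Fetub rose by 6.67 and 3.83 times and Kng1, whose air mean was under the filter level, by at least 2.63 times, above the air mean in 5 of 5 exposed mice each (Ces1g log2 2.74, SE 0.301, adjusted p = 2.18e-11). Dbp was 13.6-fold higher and Arntl 5.71-fold lower with styrene (9.61 ± 0.31 and 4.44 ± 0.53, n = 5, against 5.84 ± 1.10 and 6.95 ± 0.30, n = 4), in 5 of 5 exposed mice. The DNA demethylase Tet2 and the P450 gene Cyp1b1 fell by 5.02 and 3.98 times. Of 21 Nrf2 targets 12 rose and 1 fell, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.0455; adjusted p = 0.978 with an estimated correlation), and was not called under the stricter filter (adjusted p = 0.0653) or without the mouse labelled with a tumour (adjusted p = 0.0517). The call also ended without air replicate 1 or 3 (adjusted p = 0.0723 and 0.0543) or styrene replicate 2, 4 or 5 (adjusted p = 0.0784, 0.0582 and 0.116). WT mice had 7527 called genes, 4648 higher and 2879 lower. In KO mice the platelet genes Treml1, Gp5 and Itga2b and the serotonin transporter Slc6a4 were higher by 2.31, 2.04, 1.99 and 2.25 times (Treml1 log2 1.21, SE 0.290, adjusted p = 0.000716). The deubiquitinase Usp15 and nucleolar Nop58 were lower by 3.23 and 3.14 times. KO mice had 6176 called genes, 3753 higher and 2423 lower. TG mice, with 6 exposed and 5 air animals, had 0 called genes by limma and 980 at unadjusted p under 0.05. In TG mice adipose markers had a median of -0.79, with 4 of 9 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000173; adjusted p = 0.457 with an estimated correlation), beside heart muscle markers with a median of -0.67 (12 measured, 0 called, also when adjusted over the list alone; camera adjusted p = 2.41e-06; adjusted p = 0.553 with an estimated correlation). The adipose call ended without TG air 104 weeks replicate 1 (adjusted p = 0.0517), and 1 gene was called without TG air 104 weeks replicate 1, 2 or 5.

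At 104 weeks the differences ran along the main axis on which arrays of 1 group differed up to 78 weeks, which held 22.4% of that residual variance. Axis scores, in SD units, averaged -1.77 ± 0.40 with styrene and 0.71 ± 0.26 in air in WT (n = 5 and 4), -1.41 ± 1.16 and 0.48 ± 0.52 in KO (n = 5 and 6), -1.46 ± 0.82 and 0.80 ± 0.40 in CD-1 (n = 10 and 7) and 0.56 ± 0.66 and 0.21 ± 0.77 in TG (n = 6 and 5). The median of all genes was 0.12, 0.11 and 0.16 higher with styrene in WT, KO and CD-1. With the axis score as a covariate 228 genes were called in WT (107 higher and 121 lower), 0 in KO, 3097 in CD-1 (1933 and 1164) and 2 in TG, of which 205, 0 and 2322 had also been called without it in WT, KO and CD-1. Ces1g, Fetub, Kng1, Dbp, Arntl, Tet2 and Cyp1b1 remained called in WT with the covariate, as did the genes named for CD-1, while none of the 6 named for KO did. Tet2 and Cyp1b1 then differed by -0.94 and -1.12 in WT (adjusted p = 0.0173 and 0.00768), against -2.33 and -1.99 without it, and Ms4a1 by -1.70 in CD-1, against -2.29. Kng1 had adjusted p = 0.0457 in WT and 8.76e-08 in CD-1, and the bounds given for it hold only without the covariate. Of the 29 lists, camera called 1, 0, 9 and 3 in WT, KO, TG and CD-1 without the covariate and 12, 3, 6 and 13 with it. Each plate held 1 dose at 104 weeks in WT and CD-1, so no value within a plate can be had. Fits with a term for plate 4, which rest on placing the 2 TG or the 2 KO arrays of open plate on plate 3, called 1642 (797 higher and 845 lower) or 10 genes in WT, 0 or 0 in KO, 2938 or 62 in CD-1 and 0 or 17 in TG. In the second of these fits Aldh3a1, H2-Eb1 and Ms4a1 were not called in CD-1, nor Dbp, Fetub, Kng1, Arntl, Tet2 and Cyp1b1 in WT, and in the first neither Dbp nor Arntl in WT. In CD-1 neither fit called Dbp (0.59 and 2.06, adjusted p = 0.71 and 0.354) or Arntl (0.06 and -1.15, adjusted p = 0.958 and 0.439). Both fits ended the calls of all 6 genes named for KO and of the adipose (adjusted p = 0.199 and 0.711) and heart muscle lists (adjusted p = 0.256 and 0.843) in TG.

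**Figure D4:**
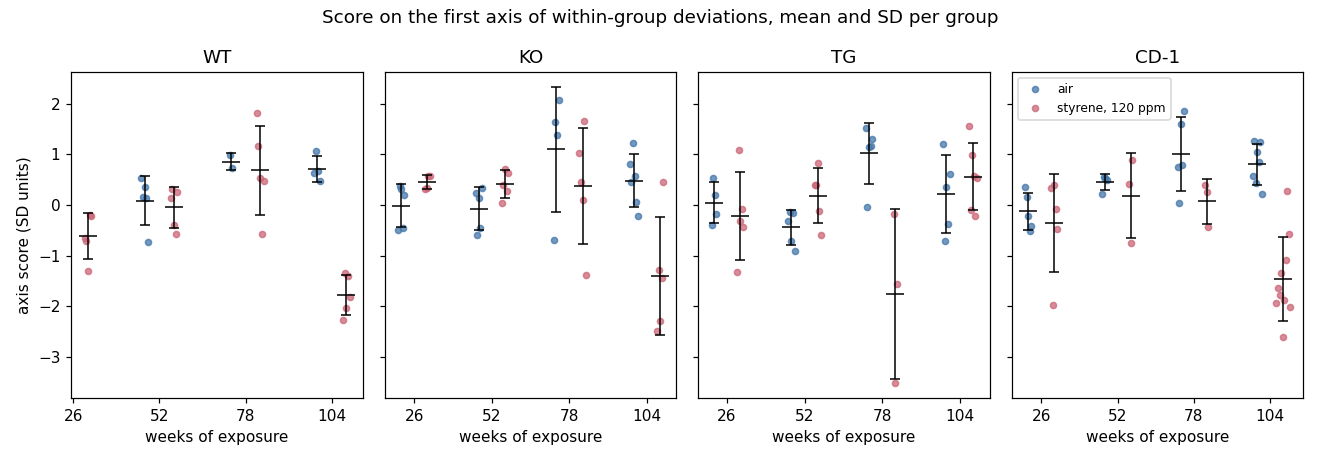
Score of each array (SD units, vertical axis) on the first axis of the differences between arrays of 1 group, against weeks of exposure for the 4 kinds of mice, with blue points for air and red for 120 ppm styrene, and the mean and SD of each group as bars. At 104 weeks the exposed WT, KO and CD-1 groups lie below their air controls, and the exposed TG group does not.

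Ageing was read from air controls at 78 against 26 weeks, all on plate 1. In KO and TG mice together, the B cell genes Bank1, Btla, Ms4a1 and H2-Ob rose by 7.22, 5.66, 5.39 and 5.19 times, and 11 of 16 B and plasma cell markers rose, also when adjusted over the list alone (median 1.31, camera adjusted p = 6.86e-06; adjusted p = 0.431 with an estimated correlation). The heat shock chaperones Hspa1b, Hsph1 and Dnajb1 fell by 24.1, 4.84 and 3.17 times (Hspa1b from 10.80 ± 0.77 to 6.23 ± 0.32, n = 9 each; log2 -4.59, SE 0.433, adjusted p = 1.96e-15), and the nuclear receptor Nr4a3 by 8.29 times. Of 10 heat shock genes 9 fell, of 20 unfolded protein response genes 15 and of 13 glucocorticoid response genes 10, as many as when adjusted over the list alone, with medians of -1.04, -0.44 and -0.86. The camera adjusted p was 2.48e-09, 4.87e-06 and 0.000433, or 0.122, 0.196 and 0.309 with an estimated correlation. Dbp rose by 5.69 times. This comparison called 6328 genes, 2580 higher and 3748 lower at 78 weeks. The axis score moved too, from -0.02 ± 0.42 and 0.04 ± 0.41 at 26 weeks to 1.10 ± 1.23 and 1.02 ± 0.60 at 78 weeks in KO and TG (n = 5, 4, 4 and 5). With it as a covariate 4616 genes were called (2247 higher and 2369 lower), 3517 of them among the 6328.

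In ageing CD-1 air controls, Hspa1b, Hsph1 and Dnajb1 fell by 23.4, 3.94 and 3.82 times (Hspa1b log2 -4.55, SE 0.577, adjusted p = 7.86e-09, n = 5 each), and Btla, Bank1 and H2-Ob rose by 4.95, 4.08 and 3.62 times. Of 20 interferon response genes 10 rose, or 11 when adjusted over the list alone (median 0.72, camera adjusted p = 5.19e-07; adjusted p = 0.325 with an estimated correlation). Of 10 heat shock genes 9 fell, also when adjusted over the list alone, and of 20 unfolded protein response genes 11, or 12 when adjusted over the list alone (camera adjusted p = 1.68e-09 and 8.36e-05; adjusted p = 0.112 and 0.325 with an estimated correlation). Dbp rose by 5.74 times. In CD-1, 3969 genes were called, 1768 higher and 2201 lower, and 2580 with the axis covariate (1335 higher and 1245 lower), 1885 of them among the 3969. The axis score averaged -0.13 ± 0.37 at 26 and 1.01 ± 0.73 at 78 weeks.

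Of the 17 CD-1 mice at 104 weeks, 7 carried a tumour label, 2 in air and 5 with styrene. The label notes tumours or lesions in the animal, while the RNA came from whole lung. With dose in the model, the cell cycle genes Ccna2, Cdk1, Top2a and Mki67 were higher in labelled mice by 3.04, 2.90, 2.65 and 2.65 times, and the protease gene Ctse by 3.44 times (log2 1.78, SE 0.427, adjusted p = 0.00308). All 27 cell cycle genes rose, also when adjusted over the list alone (camera adjusted p = 1.07e-43; 0.00413 with an estimated correlation). The mean of this list was 8.30 and 6.67 in the 2 labelled air mice against 4.79 ± 0.23 in 5 other air mice, but 4.98 ± 0.38 in 5 labelled styrene mice against 4.88 ± 0.12 in 5 other styrene mice. Among ciliated cell markers, 12 of 16 were lower, or 14 when adjusted over the list alone, led by Dnah6 and Efcab1 at 1.92 and 1.95 times lower (camera adjusted p = 1.62e-13; 0.0619 with an estimated correlation). Of 15 club cell markers 10 were lower, or 11 when adjusted over the list alone (camera adjusted p = 4.43e-10; 0.0619 with an estimated correlation). Of 23 xenobiotic metabolism genes 13 were, or 18 when adjusted over the list alone, among them Gsta2 and Cyp2e1 (camera adjusted p = 3.85e-14; 0.0175 with an estimated correlation). The heart muscle gene Myl7 was 2.70-fold lower. The 1140 called genes, 515 higher and 625 lower, fell to 5 without CD-1 air 104 weeks replicate 3, when none of the 10 genes named here was called (Ccna2 0.87, adjusted p = 0.153; Gsta2 adjusted p = 0.11). Within the air mice 4339 genes were called and the cell cycle list had adjusted p = 1.42e-56. Within the styrene mice 15 genes were called, the cell cycle list had adjusted p = 0.0843 and none of the 10 genes passed: Ccna2, Cdk1 and Mki67 differed by 0.18, 0.22 and 0.09 and Top2a by -0.11. There the ciliated, club cell and xenobiotic lists stayed lower (adjusted p = 1.44e-06, 0.0155 and 3.68e-05). All lists within a dose had the preset correlation only. With CD-1 arrays alone 28 genes were called, and of the 10 genes named here Gsta2 kept its call. With the axis covariate 1816 were called.

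**Figure D5:**
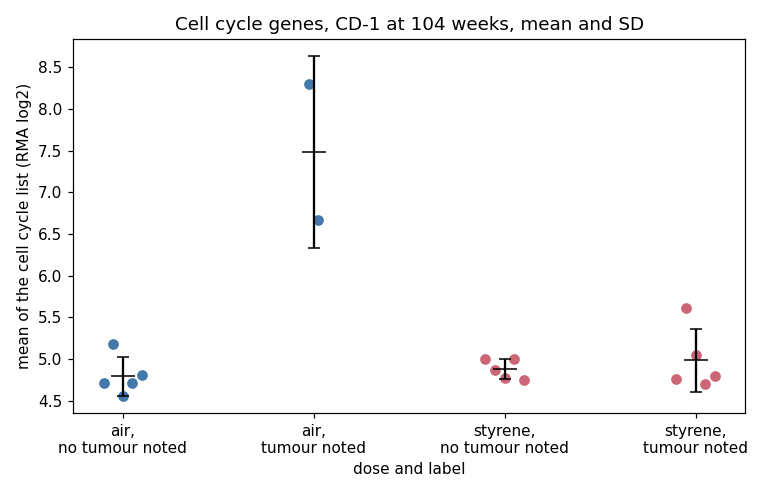
Mean of the 27 measured cell cycle genes (RMA log2 value, vertical axis) of each CD-1 array at 104 weeks, by dose and tumour label, with the mean and SD of each set as bars. The 2 labelled air mice lie at 8.30 and 6.67, above the 15 others.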

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

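The tests of explanations here were chosen after the results they bear on had been seen, except that of liver transcripts. The differences between strains were tested by contrasts fixed beforehand.

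Serpind1, Kng1, Ces1g and Fetub, genes known for their high expression in liver, rose with styrene in CD-1 lungs averaged to 78 weeks, although at 52 weeks alone Serpind1 was the single one called. Liver RNA carried along with the lung is argued against by 16 liver transcripts measured in the same average, whose median difference was -0.01 (SD 0.142) with 0 called by limma, at levels such as 12.3 for Hp, 10.7 for Trf and 3.54 for Alb. The axis along which arrays of 1 group differ is argued against as the cause for Serpind1, which kept 2.62 of its 2.69 log2 difference with the axis score as a covariate, or 97.3%. A response that needs CYP2F2 is a candidate explanation: the effect on Serpind1 was larger in WT than in KO mice by 1.47 (SE 0.223, adjusted p = 1.84e-05), while TG minus KO was -0.14 (SE 0.185, adjusted p = 1). Other differences between the WT and KO colonies, such as those seen in air, were not separated from CYP2F2.

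At 104 weeks 7527 genes were called in WT, 6176 in KO and 9977 in CD-1 mice, and 0 in TG mice. With the axis score as a covariate 0 of these remained in KO, where the axis may account for the whole count, while 205 remained in WT and 2322 in CD-1, more than the axis as the sole cause allows. A shift between plates 3 and 4 common to all strains is argued against by TG, with 4 arrays on plate 4 and 5 on plate 3, whose difference had a cosine of -0.239 with the mean of the other strains (-0.448 to 0.004 leaving out 1 TG array). A shift of handling or RNA state that spared the TG mice stays open, as each plate held 1 dose in WT and in CD-1. So does styrene itself, whose part cannot be told apart from such a shift.

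Clock genes shifted with styrene in CD-1 mice at 26 weeks, as did both lists in KO (adjusted p = 0.00237 and 0.00653 with an estimated correlation) and the Bmal1 arm in TG mice (adjusted p = 0.044). The same effect of styrene at every week is argued against by Dbp, whose difference was lower by -4.20 (SE 1.08) at 52 than at 26 weeks. A different hour of killing could give the pattern: over the 16 clock genes it had a cosine of 0.806 with the difference between 78-week and 26-week C57BL/6 air controls. At 104 weeks, where each plate held 1 dose in CD-1 and in WT, Dbp and Arntl differed by 2.27 and -1.55 in CD-1, both still called with the axis covariate and neither with a plate 4 term (adjusted p = 0.354 to 0.958), and by 3.77 and -2.51 in WT, while Dbp at 26 weeks differed by 2.67 in KO and 1.88 in TG, neither called. As no hour is given in the sources used here, sampling time and an effect of styrene at some weeks cannot be told apart.

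Stray arrays, lying far from the rest of their group, were found in 18 of 162 tests, of 6 measures in each of 27 groups of 4 to 10 arrays, where chance gives about 1 in 20. They fell in 14 groups. The mean of the cell cycle genes was 5.61 in CD-1 styrene 104 weeks replicate 4 (others 4.70 to 5.05), 5.51 in KO air 26 weeks replicate 4 (4.70 to 4.89), 5.50 in TG air 52 weeks replicate 5 (4.88 to 5.01), 5.17 in WT air 104 weeks replicate 2 (4.61 to 4.67) and 5.53 in WT styrene 78 weeks replicate 4 (4.67 to 4.80), and 4.56 in CD-1 air 52 weeks replicate 4 (4.88 to 4.92). In KO air 104 weeks replicate 6 it was 5.59 (4.68 to 4.89). That mouse carries a tumour label, which was tested in CD-1 mice and not in KO. Cyp2f2 was 12.07 in CD-1 air 104 weeks replicate 3 (12.91 to 13.41), a mouse labelled with a tumour, whose heart muscle markers averaged 4.40 (6.22 to 6.95). Cyp2f2 was 13.12 in CD-1 air 78 weeks replicate 2 (13.43 to 13.47), 11.82 in KO styrene 78 weeks replicate 5 (12.25 to 12.37) and 12.39 in TG styrene 104 weeks replicate 4 (11.89 to 12.07). Serpind1 was 5.16 in CD-1 styrene 104 weeks replicate 4 (6.50 to 7.76) and Dbp 6.03 in replicate 5 (8.78 to 9.87), both mice with a tumour label. Dbp was 6.61 in KO air 104 weeks replicate 4 (9.23 to 9.63), 7.14 in TG air 26 weeks replicate 4 (5.19 to 5.28) and 8.14 in WT styrene 26 weeks replicate 1 (9.12 to 9.45). The axis score of TG air 78 weeks replicate 2 was -0.031 (1.15 to 1.52).

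Styrene effects differed between WT and KO mice by contrasts of the fit for Serpind1 (1.47), Ces1g (1.39), Kng1 (1.28), Tcfl5 (0.94), Opn3 (0.56), Asgr1 (-2.03), Pon1 (-1.47), Ces1f (-1.31), Cldn8 (-1.21), Mfsd4a (-1.11), Itih2 and A930001A20Rik (-0.78 each), Camk2b (-0.62) and Acss1 (-0.46). Of these, Kng1 lay under the filter level in all 15 air groups and Tcfl5 in 9. They differed between CD-1 and WT mice for Serpind1 (1.18), Gsta2 (1.04), A930001A20Rik (1.00), Rhbg (0.84), Pak6 (0.75), Hsf2bp (0.66), Ptgr1 (0.60), Esyt3 (0.59), Ascc2 (0.55), Acss1 (0.47) and Hsd17b6 (0.44), which lay under that level in 12 air groups. Without WT air 78 weeks replicate 2 these 14 and 11 genes became 5 and 1, and chance cannot be excluded for either count.

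The WT styrene mice at 26 weeks, which have no air group of their week here, had Serpind1 at 6.37 ± 0.18 (n = 5, 6.11 to 6.56), against 4.65 ± 0.31 in 11 WT air mice of later weeks (4.26 to 5.12).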

How the results depend on the processing

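Except for the fits named above as added later, all alternatives were set beforehand. Cyp2f2 in KO and TG air controls against WT kept its direction and call under every alternative, from -1.32 to -1.29 leaving out each array, and against WT in KO alone from -1.34 to -1.28. Other named genes and lists were tested once under each alternative that applies to their comparison. Of these tests, without those that leave out single arrays, 1720 of genes and 625 of lists kept direction and side of the threshold, 134 and 67 lost the call in the same direction, and 2 of genes reversed. Top2a with the tumour label was -0.11 within styrene mice (adjusted p = 0.986), and Arntl in CD-1 at 104 weeks 0.06 with a plate 4 term and 2 TG arrays placed on plate 3 (adjusted p = 0.958). Leaving out single arrays, 2753 of genes and 952 of lists stayed and 298 and 10 lost the call. Counts of called genes that moved by more than 1.5 times follow. Signal near the filter level and groups of 2 or 3 arrays limit what could be called. Except where a setting itself removes samples or genes, the cause was not tested.

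Under the stricter filter, which tests fewer genes, counts were 40 in WT and 1 in TG at 52 weeks, and 12 in TG and 10 in CD-1 at 78 weeks. With C57BL/6 and CD-1 arrays fitted separately they were 124 in WT at 52 weeks, 2 in WT at 78 weeks, 1 in KO at 26 weeks, 0 in KO at 52 weeks, 0 in TG at 78 weeks, 21, 3 and 3 in CD-1 at 26, 52 and 78 weeks, 22 in CD-1 averaged, 30 for WT minus KO and 28 for the tumour label. With the axis covariate they were 183 in WT at 52 weeks, 11 and 0 in TG at 52 and 78 weeks, 175 and 18 in CD-1 at 26 and 52 weeks, 228, 0, 2 and 3097 at 104 weeks in WT, KO, TG and CD-1, 1 in KO averaged, 22 for WT minus KO, 1 for TG minus KO, 7 for CD-1 minus WT, 2580 for age in CD-1 and 1816 for the tumour label. Without a plate term they were 2 in WT and 7341 in TG at 78 weeks, 11, 1 and 2366 averaged in WT, KO and TG and 17 for CD-1 minus WT. At 104 weeks a plate 4 term gave 1642 in WT, 0 in KO and 2938 in CD-1 with 2 TG arrays placed on plate 3, and 10 in WT, 0 in KO, 17 in TG and 62 in CD-1 with 2 KO arrays placed there. Without the 2 arrays farthest along the axis they were 10 and 0 in TG at 52 and 78 weeks and 42 in CD-1 at 78 weeks. The mean of probe sets gave 37 in CD-1 at 78 weeks and 5 for CD-1 minus WT. Including 104 weeks gave averages of 122, 1 and 5084 in WT, KO and CD-1, and keeping to weeks with both doses on plate 1, without the plate 2 arrays and term, gave 72, 5 and 69. Without tumour-labelled mice WT minus KO had 28. The tumour label gave 4339 within air and 15 within styrene mice.

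Leaving out in turn each array of a comparison's own groups, counts ran from 32 to 54 for KO against WT, 35 to 55 for TG against KO and 1814 to 2806 for CD-1 against WT. For styrene at 26, 52, 78 and 104 weeks they ran from 3 to 49, 0 to 1 and 6437 to 7575 in WT (from 52 weeks), were 0, 0 to 3, 0 and 4119 to 7410 in KO and 0, 1 to 12, 0 to 2846 and 0 to 1 in TG, and from 61 to 110, 9 to 17 and 10 to 120 in CD-1 up to 78 weeks. The arrays that set the plate term in KO and TG were never left out there. Averages ran from 1 to 8 in WT, 0 to 1 in KO, 0 to 834 in TG and 60 to 194 in CD-1, WT minus KO from 5 to 20, TG minus KO from 0 to 0, CD-1 minus WT from 1 to 23, age from 5519 to 6754 in C57BL/6 and 2731 to 4130 in CD-1, and the tumour label from 5 to 1067 without either labelled air mouse.

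Replicate numbers do not pair the mice: of 64 same-numbered pairs within strain and week, 22 had deviations correlated over 0.1 (mean 0.0354, range -0.497 to 0.654). With the replicate number as a block the CD-1 count at 78 weeks was 30, the single count moved by over 1.5 times. The block ended the call of the Nrf2 list in WT at 104 weeks (adjusted p = 0.0544), of Acss1 in the WT average (adjusted p = 0.062), of Gsta2, Rhbg, Hsf2bp and Acss1 in CD-1 minus WT (adjusted p between 0.054 and 0.0654) and of Cyp2e1 with the tumour label (adjusted p = 0.263).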

Other observations

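The tests over other splits, the axis covariate fits and those of the tumour label within a dose were chosen after the results had been seen, the gene list tests before.

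Lungs of ageing C57BL/6 air controls, KO and TG together, held more signal of T and NK cell genes at 78 than at 26 weeks. The chemokine Ccl5 was 2.61-fold higher (9.72 ± 0.42 against 8.38 ± 0.46, n = 9 each; log2 1.38, SE 0.284, adjusted p = 4.74e-05) and the CD8 chain gene Cd8b1 2.19-fold higher (adjusted p = 0.000712). Of 18 measured T and NK cell markers 11 rose and 1 fell, or 12 and 1 when adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.00319; adjusted p = 0.631 with an estimated correlation). In CD-1 air controls 0 of the 18 were called by limma between these weeks, also when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.212). The difference between the 2 kinds of mice was not tested.

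Nrf2 targets, of which 17 rose with styrene in CD-1 mice at 104 weeks, were also set against the tumour label in the CD-1 mice of that week, with dose in the model. Of 21 measured, 7 were lower in labelled mice and none higher, or 9 lower when adjusted over the list alone (median -0.13, camera adjusted p = 3.08e-05; 0.107 with an estimated correlation). At the preset correlation the list was lower within air mice (adjusted p = 0.0101) and within styrene mice (adjusted p = 0.000368). So were the ciliated (adjusted p = 4.27e-08 and 1.44e-06), club cell (1.67e-08 and 0.0155) and xenobiotic lists (4.59e-10 and 3.68e-05). The glutathione transferases Gsta4 and Gstm1 were lower by 1.56 and 1.48 times (log2 -0.64, SE 0.102, and -0.57, SE 0.102; 7 labelled and 10 other mice). Neither was called without CD-1 air 104 weeks replicate 3 (-0.38, adjusted p = 0.0571, and -0.28, adjusted p = 0.177) or within styrene mice (adjusted p = 0.371 and 0.634), nor Gstm1 with CD-1 arrays alone (adjusted p = 0.0687).

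Counts of called genes, except in WT at 78 weeks with 2 air mice, were set against other splits of the same arrays, 100 per comparison with the real one included, or 35 for CD-1 at 52 weeks and 56 for CD-1 and for TG at 78 weeks. In some, only the real split, 1 of 100, reached its count, which argues against chance but is not corrected over comparisons. These were KO against WT (50 genes, 49 in the highest other split), TG against KO (54 and 43), CD-1 against WT (2732 and 299), styrene in WT at 52 weeks (63 and 22), at 104 weeks (7527 and 6721) and averaged (6 and 4), in CD-1 at 26 weeks (102 and 25) and at 104 weeks (9977 and 8124), and age in C57BL/6 (6328 and 2145) and CD-1 mice (3969 and 2268). Leaving out 1 array took KO against WT, TG against KO and WT at 52 and 104 weeks and averaged below the other split, so chance stays open there. At 104 weeks splits cannot part dose from plate. Chance is not firmly excluded where few splits reached the count, a bar luck passes in about 1 in 20 comparisons: styrene in KO at 52 weeks (2 of 100 splits, 2 genes and 2) and at 104 weeks (2 of 100, 6176 and 6409), in CD-1 averaged (2 of 100, 131 and 349) and CD-1 minus WT (4 of 100, 11 and 448).

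Chance cannot be excluded for the count of styrene in TG at 52 weeks (9 of 100 splits, 2 genes and 19), in TG at 78 weeks (8 of 56, 30 and 3569), in CD-1 at 52 weeks (12 of 35, 11 and 68) and at 78 weeks (4 of 56, 19 and 277), for WT minus KO (5 of 100, 14 and 371) or for the tumour label (8 of 100, 1140 and 2665). Where 0 genes were called, all 100 splits reach that by construction and chance was not tested. Their highest counts were 9 and 1290 in KO at 26 and 78 weeks, 27 in KO averaged, 1 and 46 in TG at 26 and 104 weeks, 982 in TG averaged and 3773 for TG minus KO. Other splits called several times the real count in TG and CD-1 at 78 weeks, WT minus KO, TG minus KO, CD-1 averaged and CD-1 minus WT, so they measure chance poorly there.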
